A study of Homo sapiens with 45 samples.

How the data were processed

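RNA sequencing was done on 22Rv1 cells, a human prostate carcinoma line, in 2 experiments with 45 samples in all. In the compound experiment, 27 libraries form 9 groups of 3: cells carrying an empty vector (EV), wild-type NONO (WT) or NONO with cysteine 145 changed to serine (C145S), each given DMSO, the R enantiomer or the S enantiomer of SKBG-1 at 20 µM for 4 h. In the knockout experiment, 18 samples form 6 groups of 3, made of control or NONO-targeted cells given a control guide or a guide against PSPC1 or SFPQ for 72 h. The labels call the replicates biological triplicates. RNA was extracted with RNeasy Plus mini kits and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols.

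For the compound experiment, the deposited values are log2(TPM + 1), where TPM is a length-corrected transcript abundance scaled to a fixed total per library, as made by the authors. The workbook that holds them is named for raw counts, but 2 to the power of each value, minus 1, summed to the TPM total in every library, so no read counts were used here. The aligner was STAR, with no version given, per the submitters' processing notes, which list builds hg38 and hg19 for these samples. The counting tool and the annotation are not given in the sources used here. TPM divides by transcript length and by the library's total, so it keeps no depth: the number of reads behind each value is unknown, no counting intervals can be given, and a transcript class that takes a large share of one library lowers every other value in it. A second sheet repeats the same values for 12 genes that the authors picked for a figure. That list was chosen on these samples and is not independent evidence of its direction.

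For the knockout experiment, the values used are log2 fold changes and adjusted p-values for 5 comparisons with the control guide, as deposited by the authors. Salmon 1.3.0, DESeq2 1.30.1 and build hg19 are named for these samples, per the submitters' processing notes. Whether fold changes were shrunk and which filter was used are not given in the sources used here. Values per library and the comparisons of double with single NONO-targeted cells were not analysed here. The table has 14535 entries. Of these, 10 had no symbol and 7 repeated the symbol of an earlier entry, which left 14518 with distinct symbols. No test was added to it: genes were counted at the authors' adjusted p under 0.05, by direction.

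The test of the compound experiment was limma 3.58.1 in R 4.3.3 with a trended prior variance, on the log2(TPM + 1) values (pseudocount 1), for the 14911 of 60232 genes with at least 1 TPM in at least 3 libraries. One coefficient per group was fitted to all 27 libraries, so that the groups shared 1 estimate of the spread. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05 and no minimum fold. A fold change on this scale understates the change of genes with low TPM. Each enantiomer was compared with DMSO within each construct, the enantiomers were compared with each other directly, the constructs were compared in DMSO, and the response to R was compared between constructs as an interaction. Because comparisons with the same DMSO libraries share their chance values, overlaps of R and S calls were not counted. The design allowed for a count model in case the files held counts, and the limma test was the one fixed for TPM values.

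The libraries differed in the share of TPM taken by 5.8S ribosomal RNA. For that reason each comparison was repeated after dividing each library's TPM by its median ratio to the mean log2 profile over genes with a mean log2 value above 3 (median-ratio scaling), after removing rRNA genes and restoring the TPM total, and without the 3 libraries over 25% in 5.8S rRNA. These 3 alternatives were chosen after seeing the data. Where median-ratio scaling moved the median of all genes by more than 0.1 on the log2 scale, the changes of the leading genes are also given relative to the median gene. The other alternatives, fixed with the design, were quantile normalization, no filter on low values, a pseudocount of 0.1, the replicate number as a block, fitting only the groups compared, a minimum log2 fold change of 1, and leaving out each library in turn. For the authors' table they were a threshold of 0.01 and a minimum log2 fold change of 1.

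Of 30 gene lists fixed before the data were examined, 29 had at least 3 tested members, and the endothelial list did not. Those reported hold the DBHS proteins (NONO, SFPQ and PSPC1), paraspeckle components, stress programmes (NRF2, heat shock, integrated stress, unfolded protein, metal and hypoxia responses), immediate early, p53, interferon and NF-kB targets, cell cycle and MYC genes, cholesterol synthesis, splicing factors, oncogenes, regulators sensitive to transcription blocks, ribosomal, mitochondrial and histone genes, and markers of luminal, basal, neuroendocrine, fibroblast and haematopoietic cells. Each list was tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 29 lists, again with an estimated correlation, and with fry, which tests whether the genes of a list move one way on balance. Camera compares the genes of a list with all other genes, so a list with a negative median can be called up where the median gene is lower still. Members called were counted with the adjusted p over all genes and adjusted over the list alone. The 12 figure genes were tested separately.

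The genes named were chosen by a fixed rule: NONO, PSPC1, SFPQ and NEAT1 in every comparison; for R against DMSO and R against S in EV cells the 8 highest and 8 lowest fold changes among genes with an adjusted p under 0.05, a mean of at least 5 TPM and no overlap between the groups; for other comparisons the 3 highest and 3 lowest; for each list called by camera in R against DMSO in EV cells up to 4 called members with the smallest p; for the authors' table the 5 highest and 5 lowest fold changes; and for each interaction the 3 genes of each sign with the smallest p. Genes without a symbol and mitochondrial or ribosomal pseudogenes were passed over. Some of the genes named by the rule and 2 of the lists are not reported here. Names are those of the files.

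Calls of R against DMSO in EV cells were compared with the authors' knockout calls, per direction, by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 10 tests. Of 12661 symbols in both tables, each test used those with an authors' adjusted p: 10289 for sgPSPC and 12656 to 12660 for the other comparisons. Gene-body lengths came from GENCODE 29 on GRCh38. They matched 99.8% of the 7385 genes with a mean of at least 5 TPM. Replicate pairs within groups correlated at 0.980 to 0.987 (Pearson's r across genes), and no pair was identical. The test was tested on simulated data: with 200 genes changed in R against DMSO in EV cells, 25.4%, 91.0% and 100% were recovered at log2 changes of 0.5, 1 and 2, with 6 unchanged genes called. For the interaction of C145S with EV the shares were 7.46%, 56.7% and 98.5%, with 3 unchanged genes called. The changed genes were drawn from those with a mean log2 level above that of 5 TPM. Each gene's noise was drawn independently, with no shift common to a library, so these counts do not cover errors from unequal rRNA shares. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.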

Results

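Transcript levels were measured by RNA sequencing of 22Rv1 cells, a human prostate carcinoma line. The compound experiment comprised 27 libraries in 9 groups of 3: empty vector (EV), wild-type NONO (WT) or NONO C145S cells given DMSO, the R enantiomer or the S enantiomer of SKBG-1 (R and S from here on) at 20 µM for 4 h. NONO, SFPQ and PSPC1 are the 3 human DBHS proteins, nuclear RNA-binding proteins that pair with each other and assemble on the long noncoding RNA NEAT1 in paraspeckles. The knockout experiment comprised 18 samples in 6 groups of 3, represented here by the authors' deposited table of 5 comparisons. On GRCh38 (GENCODE 29), NONO lies on chromosome X at 71283192 to 71301168, plus strand. PSPC1 lies on chromosome 13 at 19674752 to 19783019, minus strand, SFPQ on chromosome 1 at 35176378 to 35193148, minus strand, and NEAT1 on chromosome 11 at 65422774 to 65445540, plus strand. The depth of the libraries is unknown, because TPM keeps no depth.

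The number of genes at 1 TPM or more ranged from 11714 to 13877 per library. The share of TPM in 5.8S ribosomal RNA ranged from 6.34% to 34.2%. It was 34.2% in C145S DMSO replicate 1, 34.0% in WT DMSO replicate 2 and 28.1% in EV R replicate 1, and at most 20.0% in the other 24 libraries. The group means (± SD, n = 3) were 12.9% ± 5.06 in EV DMSO, 18.5% ± 10.5 in EV R and 8.20% ± 2.09 in EV S. They were 20.2% ± 12.1, 13.8% ± 2.48 and 13.9% ± 2.53 in WT cells with DMSO, R and S, and 18.8% ± 13.6, 13.2% ± 4.30 and 15.7% ± 3.70 in C145S cells. Mitochondrially encoded RNA took 5.40% to 12.8% of TPM, with means from 7.34% ± 0.849 in C145S S to 11.2% ± 1.41 in WT R. Genes of cytosolic ribosomal proteins took 11.9% ± 1.78 in EV R and 12.4% ± 0.609 in EV DMSO.

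**Figure D1:**
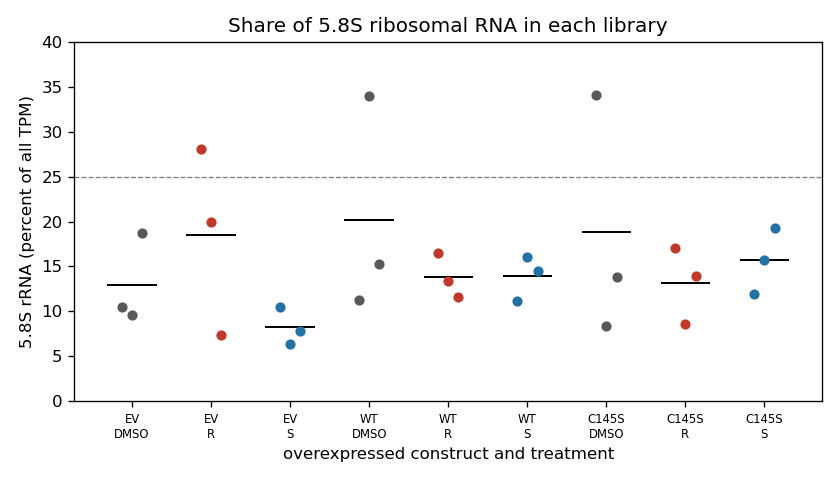
Share of TPM in 5.8S ribosomal RNA (percent, linear axis from 0) in each of the 27 libraries by group, where points are libraries, lines are group means and the dashed line is 25%. Values span 6.34% to 34.2%, and 3 libraries lie above 25%.

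The first comparison asked what the R enantiomer did to transcript levels in EV cells within 4 h. Stress genes such as HMOX1, OSGIN1 and HSPA1A rose. Of the 29 gene lists, camera called 15, of which 0 held with an estimated correlation, and fry called 12. HMOX1, haem oxygenase 1, rose from 15.2 ± 1.77 to 435 ± 129 TPM (SD, n = 3; log2 fold change 4.72, SE 0.17, adjusted p = 2.31e-15). The lowest fold changes were those of PEX14, a docking protein of peroxisomal import (-2.97, from 25.6 ± 1.56 to 2.41 ± 0.474 TPM), and SPPL3, an intramembrane protease of the Golgi (-2.66, from 14.2 ± 1.61 to 1.39 ± 0.0236 TPM). All adjusted p-values of the compound experiment are Benjamini-Hochberg values from limma. The median log2 fold change of all genes was -0.31 here and -0.09 after median-ratio scaling, so changes are also given relative to the median gene: 5.03 for HMOX1, -2.66 for PEX14 and -2.35 for SPPL3.

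Other genes that rose with R in EV cells were OSGIN1 (3.46), an oxidative stress-induced growth inhibitor, and HSPA1A (3.40), an inducible HSP70 that shares sequence with HSPA1B. CHAC1 (3.09), which degrades glutathione, rose too, as did ATF3 (2.57) and DDIT3 (2.49), transcription factors of the integrated stress response. DDIT4 (2.49), an inhibitor of mTORC1, and GDF15 (2.30), a stress-induced cytokine, were also higher. Further genes that fell were LIN52 (-2.16), a subunit of the MuvB complex, and STX18 (-2.12), a SNARE of the endoplasmic reticulum. DIAPH3 (-2.09), an actin-nucleating formin, SYTL2 (-2.02), a Rab effector, the pseudogene MLLT10P1 (-2.40) and the variant U1 snRNA gene RNVU1-27 (-2.92) fell as well. The call of RNVU1-27 (adjusted p = 0.0271) was lost after median-ratio scaling (0.067). SFPQ rose (0.35, adjusted p = 0.0205; 0.66 relative to the median gene), as did NEAT1, from 14.3 ± 1.85 to 24.8 ± 1.92 TPM (0.76, adjusted p = 0.00381; 1.07 relative to the median gene). NONO (-0.35, interval -0.70 to 0.01, adjusted p = 0.115) and PSPC1 (0.30, adjusted p = 0.122) did not pass, and PSPC1 passed after median-ratio scaling (0.56, adjusted p = 2.53e-06).

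Of 30 integrated stress response genes, 16 rose and 2 fell with R in EV cells (18 and 2 adjusted over the list alone; camera adjusted p = 3.57e-36, and adjusted p = 0.119 with an estimated correlation). Of 28 heat shock genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone; adjusted p = 0.221 with an estimated correlation), among them HSPA6 (1.92), a chaperone silent in most unstressed cells. Of 29 NRF2 targets, 10 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.301 with an estimated correlation), among them GCLM (1.52), of glutathione synthesis, and SRXN1 (1.39), which repairs peroxiredoxins. In the unfolded protein response list, 7 of 21 genes rose and 2 fell (7 and 3 adjusted over the list alone; adjusted p = 0.302 with an estimated correlation): HERPUD1 (1.61) and the chaperone HSPA5 (0.73) rose, and CREB3L2 (-0.61) fell. After median-ratio scaling 17 were higher and 1 lower. In the cholesterol synthesis list, 6 of 25 rose, among them SQLE (0.63) and HMGCS1 (0.74), and 2 fell (6 and 2 adjusted over the list alone; 18 higher and 0 lower after median-ratio scaling; adjusted p = 0.338 with an estimated correlation). Of 29 immediate early genes, 7 rose, among them JUN (1.17) and FOS (0.86), and 6 fell, among them BTG1 (-1.13), a brake on proliferation (7 and 7 adjusted over the list alone; adjusted p = 0.338 with an estimated correlation). After median-ratio scaling, 15 immediate early genes were higher and 3 lower, 26 and 1 of the integrated stress genes, 23 and 0 of the heat shock genes and 19 and 1 of the NRF2 targets. Of all 14911 genes tested, 270 were called higher, and 1248 after median-ratio scaling.

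The zinc finger factor ZBTB16 (-1.31) and the lipid phosphatase PLPP1 (-1.52) fell in the same comparison. Of 23 oncogenes of epithelial cancers, 19 fell (19 adjusted over the list alone; adjusted p = 0.521 with an estimated correlation), among them YAP1 (-1.20), the coactivator of Hippo signalling, SOX9 (-1.22) and EGFR (-0.86). Of 34 genes of G2 and M phase, 28 fell, among them ASPM (-0.72) and CDC25C (-0.75), and 0 rose (31 fell adjusted over the list alone; adjusted p = 0.822 with an estimated correlation). Such counts are to be read against all genes: 5306 of the 14911 tested were called lower, with the median gene at -0.31. All 12 genes the authors picked for a figure fell, with a median of -1.86 (12 adjusted over the list alone; p = 0.000764 with an estimated correlation), but that list was chosen on these samples and is not independent evidence.

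Camera called 15 of the 29 lists in R against DMSO in EV cells, and 0 with an estimated correlation. Fry called 12, and camera called 16 after median-ratio scaling. The estimated correlation was not computed on the scaled values. Further called lists held few called genes without scaling: metal response (1 of 9 rose, MT1H at 0.81; 0 adjusted over the list alone; adjusted p = 0.271 with an estimated correlation) and mitochondrially encoded genes (1 of 15 rose, MT-RNR2 at 0.43; 1 adjusted over the list alone; adjusted p = 0.338 with an estimated correlation). The DBHS proteins were called too (1 of 3, SFPQ; 1 adjusted over the list alone; adjusted p = 0.338 with an estimated correlation). After median-ratio scaling 7 metal response genes, 9 mitochondrially encoded genes and 2 DBHS proteins were higher and 0 lower. The haematopoietic markers were called without scaling (0 of 12 genes; 0 adjusted over the list alone; adjusted p = 0.301 with an estimated correlation), with a median (-0.03) and a test (up) that differed in sign, and that call was lost after median-ratio scaling (adjusted p = 0.146). The p53 targets were called up by the test although their median was -0.22 and 8 of 26 fell, among them XPC (-0.90) and FAS (-0.70), while 2 rose, BBC3 (0.56) being one (8 and 2 adjusted over the list alone; adjusted p = 0.822 with an estimated correlation). After median-ratio scaling 8 of the p53 targets were higher and 6 lower, so the balance of their calls turned. Cytosolic ribosomal protein genes were called up with a median of -0.10 and 1 of 39 called lower, RPS4X (-0.40). After median-ratio scaling 21 of these 39 were higher and 0 lower. So the balance of their calls turned with scaling, while the direction of the camera test was up in both. Adjusted over the list alone 0 were called, and the camera adjusted p with an estimated correlation was 0.822. Mitochondrially encoded RNA took 8.61% ± 0.919 of TPM with R and 7.49% ± 1.31 with DMSO.

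Lists without a camera call in that comparison were paraspeckle components (5 of 33 rose and 8 fell; 5 and 9 adjusted over the list alone), S phase genes (6 of 34 fell; 4) and MYC targets (10 of 32 fell; 5). Others were the interferon response (12 of 26 fell; 16), NF-kB targets (6 of 22 fell; 6), hypoxia (6 of 20 fell and 1 rose; 7 and 1) and splicing factors (7 of 33 fell; 7). Median-ratio scaling changed these counts to 9 higher and 5 lower of the paraspeckle components, which camera then called up (adjusted p = 0.0143; without scaling adjusted p = 0.822 with an estimated correlation), and to 8 and 5 of the MYC targets. The S phase genes had 4 and 3, the hypoxia genes 3 and 3, the splicing factors 4 and 3, the interferon response 0 and 5 and the NF-kB targets 0 and 3 after scaling. Among cell type markers, 8 of 16 luminal, 1 of 3 basal, 3 of 9 neuroendocrine and 1 of 8 fibroblast genes fell, with the same numbers adjusted over the list alone. Of 15 replication-dependent histone genes 3 fell (0 adjusted over the list alone), and of 15 regulators sensitive to transcription blocks 7 fell (7). Over all genes tested, 5306 of 14911 were called lower in this comparison.

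In total, 5576 genes were called in R against DMSO in EV cells, 270 higher and 5306 lower, and 643 of them by at least 2-fold, 81 higher and 562 lower. After median-ratio scaling the call was 1248 higher and 3154 lower, with quantile normalization 1651 and 1999, and without the 3 libraries over 25% in 5.8S rRNA it was 355 higher and 4708 lower. Without EV R replicate 2, 3625 genes were called.

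In WT cells, camera called 14 lists with R, and 0 with an estimated correlation. HMOX1 rose from 11.4 ± 2.45 to 364 ± 15.2 TPM (log2 fold change 4.89, SE 0.17) and HSPA1A by 3.60. The lowest fold changes were those of PEX14 (-2.58), SPPL3 (-2.46) and RAB40C, a substrate receptor of a ubiquitin ligase (-2.29, from 14.7 ± 1.14 to 2.22 ± 0.0714 TPM). The small nucleolar RNA gene SNORA31 was listed at 0 in all 3 DMSO libraries. SFPQ (0.47, adjusted p = 0.00377) and NEAT1 (0.59, adjusted p = 0.0239) rose, and NONO (0.30, adjusted p = 0.225) and PSPC1 (0.12, adjusted p = 0.605) did not pass.

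Of the lists in WT cells with R, 16 of 30 integrated stress genes rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 0.294 with an estimated correlation). Heat shock genes rose in 14 of 28 cases (16 adjusted over the list alone; adjusted p = 0.294 with an estimated correlation). Cholesterol synthesis genes rose in 14 of 25 cases and fell in 1 (15 and 1 adjusted over the list alone; adjusted p = 0.328 with an estimated correlation). Mitochondrially encoded genes rose in 10 of 15 cases (14 adjusted over the list alone; adjusted p = 0.328 with an estimated correlation), and their share of TPM was 11.2% ± 1.41 with R and 7.45% ± 2.10 with DMSO. With R, 15 of 23 oncogenes fell (16 adjusted over the list alone; adjusted p = 0.571 with an estimated correlation). All 12 figure genes fell (12 adjusted over the list alone; median -1.78), again on samples they were chosen from. After median-ratio scaling 23 integrated stress, 22 heat shock, 16 cholesterol synthesis and 15 mitochondrially encoded genes were higher. In total 3677 genes were called, 397 higher and 3280 lower. After median-ratio scaling 1559 were higher and 3681 lower, with quantile normalization 2069 and 2248, and without WT DMSO replicate 1 the count was 2411.

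In C145S cells, camera called 18 lists with R, and 0 with an estimated correlation. HMOX1 rose from 10.2 ± 1.74 to 434 ± 32.9 TPM (log2 fold change 5.30), OSGIN1 by 3.75 and HSPA1A by 3.64. The lowest fold changes were those of MAD1L1, a spindle checkpoint protein (-1.75, adjusted p = 1.03e-07), LRRC26, a potassium channel subunit (-1.57, adjusted p = 0.0468), and the pseudogene MLLT10P2 (-1.53, adjusted p = 0.00995). PSPC1 rose from 15.4 ± 4.13 to 28.1 ± 3.21 TPM (0.86, adjusted p = 0.000868), SFPQ rose (0.67, adjusted p = 0.000649) and so did NEAT1 (0.76, adjusted p = 0.0182), and NONO did not pass (0.21, adjusted p = 0.577).

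Integrated stress genes rose in 20 of 30 cases in C145S cells with R (23 rose and 1 fell adjusted over the list alone; adjusted p = 0.105 with an estimated correlation), and heat shock genes in 16 of 28 (22; adjusted p = 0.11 with an estimated correlation). NRF2 targets rose in 15 of 29 (18; adjusted p = 0.11 with an estimated correlation) and cholesterol synthesis genes in 13 of 25 (16 rose and 1 fell; adjusted p = 0.239 with an estimated correlation). Oncogenes fell in 3 of 23 cases (4; adjusted p = 0.829 with an estimated correlation), G2 and M phase genes in 1 of 34 (1; camera adjusted p = 0.138, and 0.0187, down, after median-ratio scaling with 1 higher and 5 lower; without scaling adjusted p = 0.866 with an estimated correlation), and 8 of the 12 figure genes fell (8; median -0.63). After median-ratio scaling 24 integrated stress, 23 heat shock, 18 NRF2 and 16 cholesterol synthesis genes were higher, and 8 oncogenes lower. In total 766 genes were called, 331 higher and 435 lower. With rRNA genes removed 703 were higher and 2137 lower, and with quantile normalization 1339 and 1401. Fitting only the groups compared gave 38 calls, 34 higher and 4 lower. The count was 1185 without C145S DMSO replicate 1, 471 without C145S DMSO replicate 3, 426 without C145S R replicate 3 and 1522 without the 3 libraries over 25% in 5.8S rRNA.

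**Figure D2:**
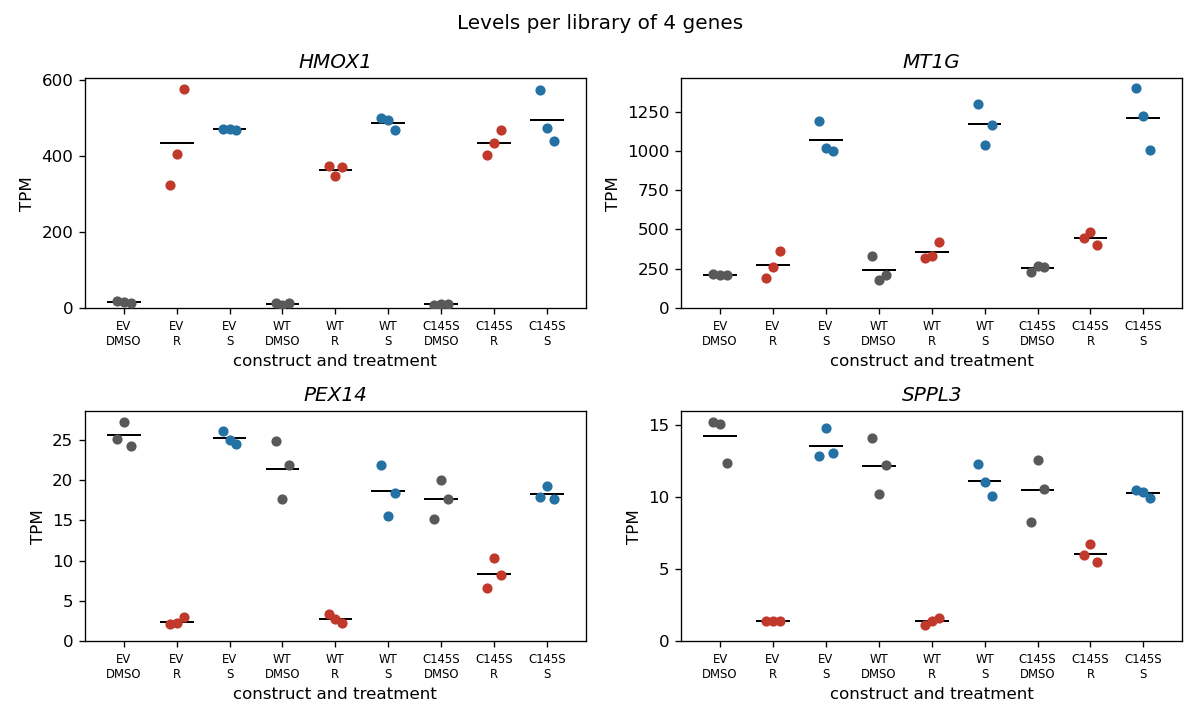
TPM (linear axes from 0) of HMOX1, MT1G, PEX14 and SPPL3 in each of the 27 libraries by group, where points are libraries and lines are group means. HMOX1 lay at 10.2 to 15.2 TPM on average with DMSO and at 364 to 495 TPM with either enantiomer, and SPPL3 fell to 1.39, 1.37 and 6.05 TPM with R in EV, WT and C145S cells.

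The S enantiomer was compared with DMSO in each construct to ask which changes the other stereoisomer gave at the same dose and time. HMOX1, OSGIN1, HSPA1A and MT1G rose in all 3 constructs. HMOX1 reached 470 ± 1.21, 487 ± 16.4 and 495 ± 70.5 TPM in EV, WT and C145S cells (log2 fold changes 4.87, 5.32 and 5.48), and OSGIN1 (3.44, 3.60 and 4.00) and HSPA1A (3.51, 3.73 and 3.97) rose too. MT1G, a metallothionein of a family with near-identical members, rose by 2.33, 2.33 and 2.24, from 210.6 ± 4.59 to 1069 ± 106 TPM in EV cells. The genes lowest with R did not pass with S: PEX14 was at -0.02 (interval -0.34 to 0.30) and SPPL3 at -0.06 (-0.33 to 0.21) in EV cells.

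Of 9 metal response genes, 8 rose with S in each construct (9, 8 and 9 adjusted over the list alone), and the camera call held with an estimated correlation (adjusted p = 0.000209, 0.000509 and 0.0017). Of 30 integrated stress genes, 21, 19 and 22 rose in EV, WT and C145S cells (25, 25 and 27 adjusted over the list alone; adjusted p = 0.00763, 0.0094 and 0.0099 with an estimated correlation). Of 28 heat shock genes, 13, 13 and 16 rose (16, 19 and 23 adjusted over the list alone; adjusted p = 0.0553, 0.0316 and 0.0257 with an estimated correlation), and of 29 NRF2 targets 10, 11 and 14 (17, 16 and 24; adjusted p = 0.0553, 0.0497 and 0.0267 with an estimated correlation). After median-ratio scaling 26, 25 and 26 integrated stress genes, 18, 21 and 21 heat shock genes and 17, 17 and 21 NRF2 targets were higher with S. G2 and M phase genes were called down in all 3 constructs with 1, 0 and 1 genes called (4, 2 and 6 adjusted over the list alone; 9, 9 and 16 lower after median-ratio scaling; adjusted p = 0.569, 0.723 and 0.508 with an estimated correlation).

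Genes that fell with S were LBX2, a homeobox gene, in all 3 constructs (-1.34, -1.45 and -1.38), and EEF1A1P5 in EV cells (-1.28), a pseudogene near-identical to EEF1A1. So did the glycosyltransferase B4GAT1 (-0.94) and PRR15L (-0.91) in WT cells, and RGS14 (-1.14) in C145S cells. USP41 was listed at 0 in all 3 EV libraries with S. NEAT1 rose in C145S cells (0.96, adjusted p = 0.00368) and did not pass in EV (0.70, adjusted p = 0.0633) or WT cells (0.50, adjusted p = 0.298). NONO (0.04, 0.17 and 0.56), SFPQ (0.07, 0.28 and 0.23) and PSPC1 (0.13, 0.28 and 0.16) did not pass in any construct. Of the 12 figure genes 0, 0 and 1 fell (0, 0 and 1 adjusted over the list alone).

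In EV cells 279 genes were called with S, 176 higher and 103 lower (518 and 546 after median-ratio scaling; 349 and 812 with rRNA genes removed). The count was 173 without EV S replicate 1. In WT cells 214 were called, 156 higher and 58 lower (549 and 589 after median-ratio scaling; 310 and 1092 with rRNA genes removed). The count was 136 without WT DMSO replicate 3, 138 without WT S replicate 1, 141 without WT S replicate 2 and 140 without WT S replicate 3. In C145S cells 338 were called, 267 higher and 71 lower (710 and 864 after median-ratio scaling; 709 and 527 with rRNA genes removed). The count was 745 without C145S DMSO replicate 2, 199 without C145S S replicate 1 and 216 without C145S S replicate 2. Fitting only the groups compared gave 81 calls in WT cells, 74 higher and 7 lower, and 81 in C145S cells, 73 and 8. Camera called 11, 15 and 15 lists, of which 2, 4 and 5 held with an estimated correlation.

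The enantiomers were then compared directly, at 20 µM and 4 h in each construct. In EV cells, genes were lower with R than with S far more often than higher, a difference was not shown for the stress genes that rose most, and the metallothionein genes MT1M and MT1G were lower with R. PEX14 (-2.95, interval -3.27 to -2.63), SPPL3 (-2.60, -2.87 to -2.33), STX18 (-2.24), ZFAND3 (-2.10) and LIN52 (-2.07) were lower with R. MT1M (-2.13, -2.62 to -1.64) and MT1G (-2.02, -2.43 to -1.61; 270.5 ± 85.1 against 1069 ± 106 TPM) were lower too. Relative to the median gene, which lay at -0.28 (-0.05 after median-ratio scaling), the differences were -2.67 for PEX14, -2.32 for SPPL3 and -1.74 for MT1G.

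Genes higher with R than with S in EV cells included PAWR, a proapoptotic regulator (1.03; 1.31 relative to the median gene). COG3 (0.97), of the Golgi tethering complex, SSH2 (0.92), a cofilin phosphatase, FOXP1 (0.91), a forkhead factor, and the pseudogene EEF1A1P5 (1.28 relative to the median gene) were higher as well. SERF1A (-3.96, adjusted p = 0.0468; 0.113 after median-ratio scaling) and SERF1B (3.90) are near-identical copies, so their values are uncertain, and RNU4-2 was listed at 0 in the S libraries. NEAT1 (0.06, interval -0.33 to 0.45), PSPC1 (0.17, adjusted p = 0.395), SFPQ (0.28, adjusted p = 0.0712) and NONO (-0.39, -0.75 to -0.03, adjusted p = 0.0916) did not pass.

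A difference between R and S was not shown in EV cells for HMOX1 (-0.15, interval -0.50 to 0.19), OSGIN1 (0.02, -0.23 to 0.27), HSPA1A (-0.12, -0.51 to 0.28), CHAC1 (0.08, -0.18 to 0.34), DDIT3 (0.05, -0.25 to 0.34), DDIT4 (-0.02, -0.37 to 0.32), ATF3 (-0.35, -0.75 to 0.05) or GDF15 (-0.22, -0.53 to 0.08). These intervals leave room for differences of up to the bound farther from 0. After median-ratio scaling OSGIN1 passed as higher with R in EV cells (adjusted p = 0.00212). In WT cells OSGIN1 was lower with R (-0.38, -0.62 to -0.13, adjusted p = 0.033), and HMOX1 did not pass (-0.42, -0.77 to -0.08, adjusted p = 0.094). In C145S cells the differences were -0.18 for HMOX1 (-0.53 to 0.16), -0.26 for OSGIN1 (-0.50 to -0.01) and -0.33 for HSPA1A (-0.73 to 0.06), with none past the threshold.

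Of 9 metal response genes, 8 were lower with R than with S in each construct (8 each adjusted over the list alone), with medians of -1.62, -1.47 and -1.29 in EV, WT and C145S cells. The call held in C145S cells (adjusted p = 0.00948 with an estimated correlation) and was lost in EV (adjusted p = 0.0798 with an estimated correlation) and WT cells (adjusted p = 0.334 with an estimated correlation). Of 23 oncogenes, 16 were lower in EV cells (19 adjusted over the list alone; adjusted p = 0.995 with an estimated correlation) and 6 in WT cells (10; adjusted p = 0.972 with an estimated correlation), and after median-ratio scaling 9 were lower in EV and 9 lower and 1 higher in WT cells. In EV cells the paraspeckle, unfolded protein, cholesterol and cytosolic ribosomal protein lists were called up although their medians were -0.19, -0.08, -0.13 and -0.13, and all 4 calls were lost (adjusted p = 0.995 with an estimated correlation). Of their genes, 2 were higher and 6 lower, 0 and 3, 0 and 0, and 0 and 0 (the same numbers adjusted over the list alone), which turned to 8 and 1, 9 and 2, 10 and 0, and 8 and 0 after median-ratio scaling. In WT cells the cytosolic ribosomal proteins were called up with a median of -0.04 and 0 of 39 called (0 adjusted over the list alone; 10 higher after median-ratio scaling; adjusted p = 0.972 with an estimated correlation). The 12 figure genes were lower in 12, 12 and 8 cases (12, 12 and 9 adjusted over the list alone), on samples they were chosen from.

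In WT cells STX18 (-2.47), PEX14 (-2.39) and TOX3, an HMG-box factor (-2.38), were lowest with R, and USP12, a deubiquitinase (1.64), MSI2, an RNA-binding protein (1.46), and SSH2 (1.31) highest. Relative to the median gene, at -0.17, STX18 was at -2.31 and PEX14 at -2.22. In C145S cells MT1M (-2.05), MAD1L1 (-1.72, -2.05 to -1.39) and MT1F (-1.62) were lowest and FOXP1 (1.41), DMC1, a meiotic recombinase (1.02), and SSH2 (0.72, adjusted p = 0.0499) highest. There PSPC1 was higher (0.70, 0.39 to 1.01, adjusted p = 0.0162), SPPL3 lower (-0.68, -0.95 to -0.41) and PEX14 lower (-1.06). NEAT1 did not pass in WT (0.09, -0.30 to 0.49) or C145S cells (-0.20, -0.59 to 0.19), nor did NONO (0.13 and -0.36) or SFPQ (0.19 and 0.44, adjusted p = 0.3 and 0.0572).

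Between R and S, 4074 genes were called in EV cells, 129 higher and 3945 lower (595 and 2011 after median-ratio scaling). The calls numbered 2323 in WT cells, 112 higher and 2211 lower (827 and 2356), and 205 in C145S cells, 27 higher and 178 lower (565 and 634). With quantile normalization they were 714 higher and 1278 lower in EV, 1268 and 1566 in WT, and 619 and 551 in C145S cells. Fitting only the groups compared gave 91 and 2541 in EV and 8 and 26 in C145S cells. The EV count was 2375 without EV R replicate 1, 2200 without EV R replicate 2 and 2567 without EV S replicate 2, and the WT count 1517 without WT S replicate 1. The C145S count was 101, 115, 97, 79 and 134 without C145S R replicate 1, C145S R replicate 3, C145S S replicate 1, C145S S replicate 2 and C145S S replicate 3, and 401 without the 3 libraries over 25% in 5.8S rRNA.

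**Figure D3:**
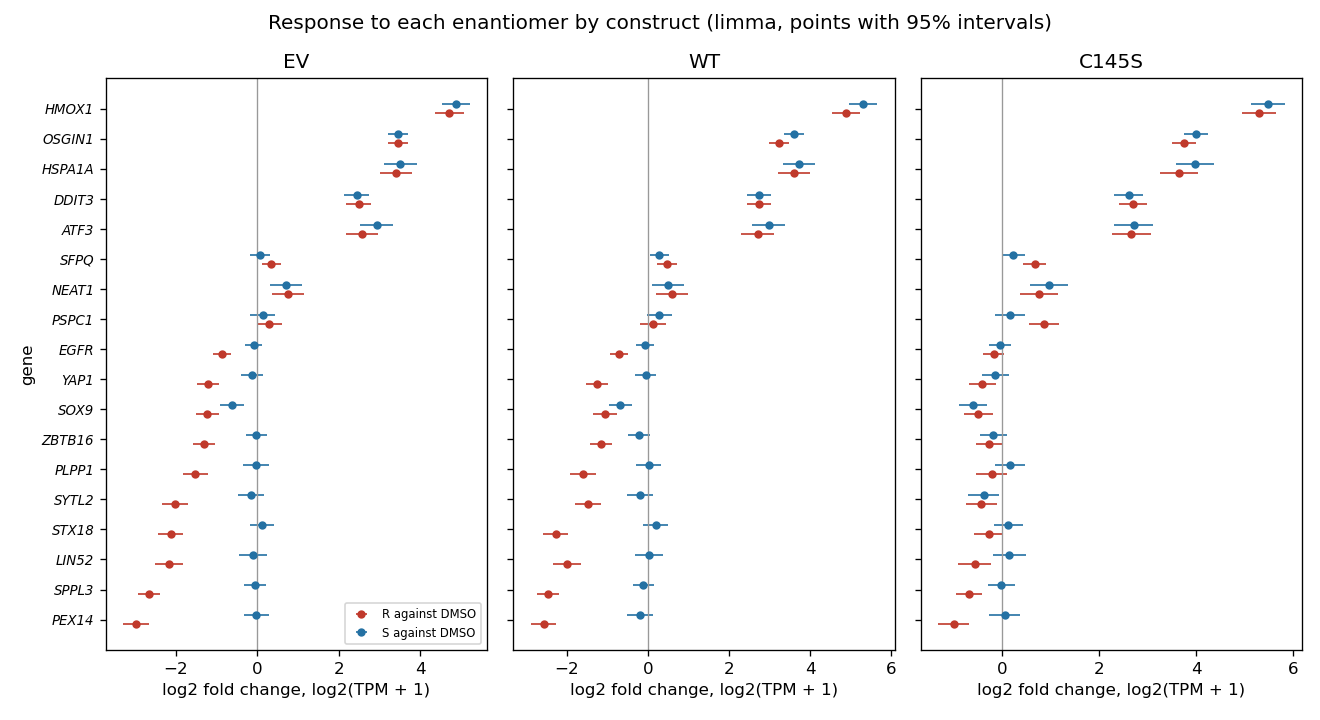
Log2 fold change against DMSO of 18 genes with the R and S enantiomers in EV, WT and C145S cells, where points are limma estimates and bars are 95% intervals (n = 3 libraries per group). In EV cells HMOX1 lay at 4.72 with R and 4.87 with S, and SPPL3 at -2.66 with R and -0.06 with S.

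Gene-body length was examined after the values had been seen. With median-ratio scaling, the median log2 difference between R and S in EV cells went from 0.07 for genes under 10 kb to -0.39 for 186 genes of 200 to 500 kb. In WT cells it went from 0.05 to -0.41 and in C145S cells from -0.01 to -0.13. For the 23 genes over 500 kb the values were nearer 0, at -0.35, -0.22 and -0.09. Of the 209 genes of at least 200 kb, 52.2% were called lower with R than with S in EV cells after median-ratio scaling, and of the 5617 genes under 50 kb, 6.71%.

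**Figure D4:**
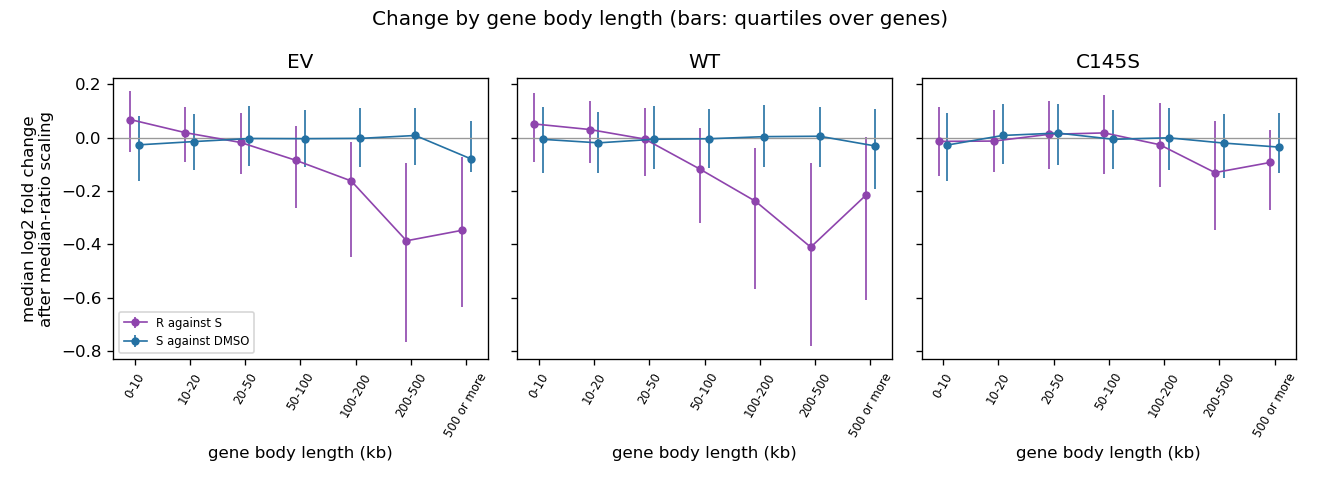
Median log2 difference after median-ratio scaling (points) with quartiles (bars) by gene-body length (kb), for R against S and S against DMSO in each construct. For R against S the medians of genes of 200 to 500 kb were -0.39 in EV, -0.41 in WT and -0.13 in C145S cells.

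The constructs were compared in DMSO to check the expressed NONO and its own effect. NONO was at 57.2 ± 1.51 TPM in EV, 585 ± 73.0 in WT and 408 ± 117 in C145S cells (log2 fold changes against EV of 3.32, adjusted p = 2.05e-11, and 2.77, adjusted p = 9.49e-10), and WT and C145S did not differ past the threshold (-0.55, interval -0.91 to -0.19, adjusted p = 0.43). NEAT1 was lower than in EV cells, at 14.3 ± 1.85 TPM, in WT (7.33 ± 0.687; -0.87, adjusted p = 0.0373; 0.192 after median-ratio scaling) and C145S cells (5.29 ± 1.03; -1.29, adjusted p = 0.000286). Relative to the median gene, which lay at -0.23 in WT and -0.38 in C145S cells (-0.03 and -0.07 after median-ratio scaling), NEAT1 was at -0.64 and -0.91. PSPC1 was lower in C145S cells (-0.69, adjusted p = 0.00194; -0.32 relative to the median gene) and did not pass in WT cells (-0.57, adjusted p = 0.0742). SFPQ did not pass in either (-0.12 and -0.21).

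Among other genes, the pseudogene EEF1A1P5 (-1.37) and IMMP2L, of the mitochondrial inner membrane peptidase (-1.49, adjusted p = 0.000502), were lower and S100A1, a calcium-binding protein (0.93, adjusted p = 0.0373), higher in WT than in EV cells. In C145S cells RNVU1-27 (-3.17, adjusted p = 0.0147; 0.0709 after median-ratio scaling) and the muscle troponin gene TNNC2 (-2.01, adjusted p = 0.00549) were lower and RPPH1, the RNA of RNase P, higher (1.41, adjusted p = 0.0129). SCARNA21 was listed at 0 in the EV libraries and SNORA65 in the C145S libraries. Between C145S and WT cells, S100A1 was lower (-1.27, adjusted p = 0.00799), with NEAT1 at -0.42 (adjusted p = 0.436), PSPC1 at -0.12 and SFPQ at -0.09. GPHA2 and TNNC1, chosen after their values were seen, made up the rest of the 3 calls, at -2.07 and -1.53. Relative to the median gene, at -0.15 (-0.03 after median-ratio scaling), S100A1 was at -1.12, GPHA2 at -1.92, TNNC1 at -1.38, NEAT1 at -0.26 and NONO at -0.40.

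Of 34 G2 and M phase genes 31 were lower in C145S than in EV cells (31 adjusted over the list alone; adjusted p = 0.866 with an estimated correlation), and after median-ratio scaling 13 were lower and 2 higher. Mitochondrially encoded genes were called up with 0 of 15 called (0 adjusted over the list alone; adjusted p = 0.268 with an estimated correlation), and 13 after median-ratio scaling. Cytosolic ribosomal proteins had 1 higher and 5 lower (0 adjusted over the list alone, camera adjusted p = 0.866 with an estimated correlation). This balance of calls turned with median-ratio scaling (32 higher and 0 lower), while the direction of the camera test was up in both. The histone call held with an estimated correlation against EV in C145S (adjusted p = 0.00778) and WT cells (adjusted p = 0.0173), with 2 higher and 2 lower of 15 in C145S and 0 called in WT cells (1 and 1, and 0, adjusted over the list alone). In C145S cells the test called the histones up, with a median log2 fold change of 0 and a mean of 0.07. In these comparisons test and median also differed in sign for the DBHS proteins in both, the NF-kB targets, ribosomal and mitochondrial genes in WT, and the haematopoietic markers and ribosomal genes in C145S cells.

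In DMSO, 73 genes were called between WT and EV cells, 5 higher and 68 lower (12 and 30 after median-ratio scaling). The calls numbered 7303 between C145S and EV cells, 60 higher and 7243 lower (983 and 1772), and 3 between C145S and WT cells, all lower (2 higher and 6 lower). With rRNA genes removed there were 28 higher and 1692 lower between C145S and WT cells. Fitting only the groups compared gave 8 higher and 31 lower between C145S and EV cells, and 3 and 3 between WT and EV cells. Between C145S and WT cells it gave 2 higher and 1 lower, of which 1 was among the 3 genes called above. The 5.8S rRNA share was 12.9% ± 5.06, 20.2% ± 12.1 and 18.8% ± 13.6 in EV, WT and C145S DMSO. Without C145S DMSO replicate 1 the C145S against EV count was 2780, and without WT DMSO replicate 2 the C145S against WT count was 5 and without C145S DMSO replicate 2 it was 168. The WT against EV count was 30, 33 and 36 without EV DMSO replicates 1, 2 and 3, and 211, 17 and 24 without WT DMSO replicates 1, 2 and 3.

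Whether the response to R depends on the construct was tested as an interaction. Between C145S and EV cells 572 genes differed, 563 with a higher log2 change in C145S cells and 9 with a lower one (406 and 61 after median-ratio scaling). MED13L, of the Mediator kinase module (difference 1.64), had the smallest p, followed by SPPL3 (1.97, interval 1.59 to 2.36, limma adjusted p = 1.8e-06) and the kinesin KIF21A (1.56). EID3 (-1.05), SFT2D3 (-0.77) and the pseudogene CHMP4BP1 (-1.49) led the other sign. All of these lay under 1 TPM in every DMSO library, and SFT2D3 reached at most 0.85 TPM in EV cells with R. Relative to the median gene, at 0.31 (0.05 after median-ratio scaling), the difference was 1.66 for SPPL3. PSPC1 (0.56, adjusted p = 0.119), SFPQ (0.32), NEAT1 (0.01) and NONO (0.55) did not pass.

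Between C145S and WT cells 573 genes differed in the response to R, 552 with a higher change in C145S cells and 21 with a lower one (932 and 126 after median-ratio scaling). RASSF3, a Ras association domain protein (2.08, adjusted p = 3.82e-07), BCAR1, a focal adhesion scaffold (1.87), and CUL3, the cullin that with KEAP1 marks NRF2 for degradation (1.84), had the smallest p. GZMM (-1.72), SFT2D3 (-1.24) and EID3 (-1.24) led the other sign, and all of these lay under 1 TPM in every DMSO library. Relative to the median gene, at 0.18, the difference was 1.90 for RASSF3. PSPC1 (0.73, adjusted p = 0.0552), SFPQ (0.20), NEAT1 (0.17) and NONO (-0.09) did not pass. Between WT and EV cells 3 genes differed, VPS8, of an endosomal tethering complex (0.94, adjusted p = 0.0471), BCAR1 (-1.12, adjusted p = 0.0108), and 1 that has a clone name only (1.49, adjusted p = 0.00907), with 13 higher and 114 lower after median-ratio scaling and a median gene at 0.12 (0.82 for VPS8 and -1.24 for BCAR1 relative to it). There NONO was at 0.65 (adjusted p = 0.894), PSPC1 at -0.17, SFPQ at 0.12 and NEAT1 at -0.16.

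Of the 12 figure genes, 8 fell less with R in C145S than in EV cells (11 adjusted over the list alone; median difference 0.99; p = 0.00185 with an estimated correlation), 9 less than in WT cells (10; 1.03; p = 0.00107 with an estimated correlation), and 0 differed between WT and EV cells in limma, on samples they were chosen from. Of 23 oncogenes 6 differed between C145S and EV cells (6 adjusted over the list alone; adjusted p = 0.99 with an estimated correlation) and 4 between C145S and WT cells (5; adjusted p = 0.997 with an estimated correlation), all higher. Mitochondrially encoded genes were called down between C145S and WT cells with 0 of 15 called (0 adjusted over the list alone; adjusted p = 0.296 with an estimated correlation; 9 after median-ratio scaling). Of all lists, camera called 4, 7 and 5 in WT minus EV, C145S minus EV and C145S minus WT, and 0 with an estimated correlation.

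The C145S minus EV count was 195 without C145S DMSO replicate 1, 3551 without C145S DMSO replicate 2, 361 without C145S DMSO replicate 3, and 967, 215 and 312 without C145S R replicates 1, 2 and 3. It was 250 and 248 without EV DMSO replicates 1 and 2, 265, 225 and 2024 without EV R replicates 1, 2 and 3, and 155 without the 3 libraries over 25% in 5.8S rRNA. The C145S minus WT count was 331 without C145S DMSO replicate 1, 1253 without C145S DMSO replicate 2, 335 without C145S R replicate 2 and 325 without WT DMSO replicate 1. Fitting only the groups compared gave 58 higher and 0 lower for C145S minus EV and 142 and 14 for C145S minus WT. The WT minus EV count was 1 without EV R replicate 3, 0 without WT DMSO replicate 1 (limma; 1290 at an unadjusted p under 0.05) and 1 without WT DMSO replicate 3.

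In the knockout experiment, the authors' deposited table was read first for the targeted genes. In that table NONO was lower with sgNONO (log2 fold change -3.23, authors' adjusted p = 4.45e-250), sgSFPQ with sgNONO (-3.26) and sgPSPC with sgNONO (-3.61), and SFPQ was lower with sgSFPQ (-2.06, authors' adjusted p = 4.65e-74) and sgSFPQ with sgNONO (-2.04). PSPC1 was lower with sgPSPC alone (-0.42, authors' adjusted p = 0.00307), at 0.03 with sgPSPC and sgNONO (0.869), and higher with sgSFPQ (0.64), sgNONO (0.68) and both (1.13). NEAT1 was lower with sgNONO (-0.61, authors' adjusted p = 0.000458) and with sgPSPC and sgNONO (-1.12, 4.23e-11), and did not pass with sgSFPQ (0.21), sgPSPC (0.01) or sgSFPQ and sgNONO (-0.25, 0.155). Transcript levels do not show whether protein was lost.

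**Figure D5:**
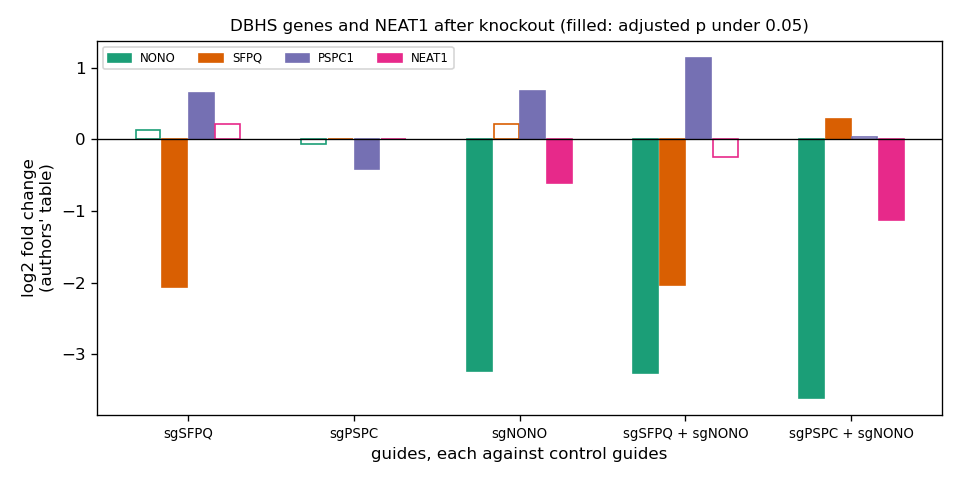
Log2 fold change against the control guide of NONO, SFPQ, PSPC1 and NEAT1 in the 5 comparisons of the authors' deposited table, where filled bars have an authors' adjusted p under 0.05. NONO lay at -3.23 to -3.61 in the 3 comparisons with sgNONO, and NEAT1 at -1.12 with sgPSPC and sgNONO.

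The authors' deposited table called 2683 genes with sgNONO (1399 higher, 1284 lower), 2556 with sgSFPQ (1238 and 1318), 509 with sgPSPC (172 and 337), 6553 with sgSFPQ and sgNONO (3231 and 3322), and 3484 with sgPSPC and sgNONO (1715 and 1769). With sgNONO the lowest were SLC17A2, a phosphate transporter (-6.58), and the homeobox gene PROX1 (-6.01), and the highest CHRNA4, a nicotinic receptor subunit (9.83), the long noncoding RNA THRIL (8.68) and NTRK2, the BDNF receptor (5.74). With sgSFPQ they were RAB3C (-4.27), GPM6A (-3.41) and GPC6 (-2.86) against CHRNA2 (12.09), CHRNA4 (9.90) and EMX1 (6.21). With sgPSPC the range was from ZBTB20, a zinc finger repressor (-1.21), to VIM, vimentin (0.53). With sgSFPQ and sgNONO, PROX1-AS1 (-8.45) and SLC17A2 (-8.20) were lowest and MSMB, a secreted prostate protein (7.39), and CGA, the glycoprotein hormone alpha chain (7.27), highest. With sgPSPC and sgNONO, SLC17A2 (-8.82) and PROX1-AS1 (-7.58) were lowest and NTRK2 (5.87) and BHLHE41, a clock repressor (5.13), highest. No minimum level was applied in choosing these genes, and the levels behind their fold changes were not examined.

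By list in the authors' deposited table, 24 of 35 S phase genes were lower with sgSFPQ and 27 lower and 1 higher with sgSFPQ and sgNONO, and 14 and 12 of 34 G2 and M phase genes were lower. With sgNONO alone 5 S phase and 5 G2 and M phase genes were higher and 0 lower. Cytosolic ribosomal proteins were higher in 24 and 18 of 39 cases, and replication-dependent histones in 5 and 9 of 11. With sgSFPQ and sgNONO 21 of 32 MYC targets were lower, 16 of 26 p53 targets higher and 3 lower, and 17 of 31 immediate early genes higher and 2 lower. There 14 of 21 unfolded protein response genes were lower and 1 higher. Integrated stress genes were lower in 8 of 30 cases and higher in 1 with sgNONO, and 11 and 1 with sgPSPC and sgNONO. With sgSFPQ and sgNONO 8 were higher and 5 lower, with sgSFPQ 2 and 3, and with sgPSPC 0 and 2. Of the 12 figure genes, 9 were lower and 1 higher with sgSFPQ and sgNONO, 4 and 0 with sgSFPQ, 2 and 2 with sgNONO, 4 and 1 with sgPSPC and sgNONO, and 0 and 0 with sgPSPC. These lists were counted without a set test, since the table holds no libraries.

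The calls of R against DMSO in EV cells were compared with those of the authors' deposited table, from other libraries. Genes lower with R were lower with sgSFPQ more often than independent lists would be (686 shared, 461 expected; odds ratio 2.40, interval 2.11 to 2.72, Fisher's exact adjusted p = 1.71e-43). The odds ratio was 1.66 with sgSFPQ and sgNONO (adjusted p = 8.95e-32), 1.22 with sgPSPC and sgNONO (0.00101), 1.15 with sgNONO (0.0456) and 0.85 with sgPSPC (0.223). For genes higher with R it was 2.34 with sgSFPQ and sgNONO (adjusted p = 2.78e-07), 1.97 with sgSFPQ (0.00336), 1.78 with sgPSPC and sgNONO (0.00625), 1.33 with sgNONO (0.223) and 0.79 with sgPSPC, where 2 genes were shared. Genes are not independent, so these p-values describe the overlap of the lists, and after median-ratio scaling of the compound calls the overlap of lower genes with sgNONO (1.13, adjusted p = 0.156) and that of higher genes with sgPSPC and sgNONO (1.07, adjusted p = 0.494) lost their calls.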

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

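The spread of a share over left-out libraries, and the tests of the response in C145S against WT cells, of the long-gene difference after median-ratio scaling and of that difference between constructs were chosen after the result was seen. The results in the next paragraphs stand here because a test of the difference between constructs (the limma interaction of R against DMSO) passed for them. No group held 4 samples, so no search for single samples far from their group was made. Splits that mix constructs also hold the difference between constructs, so for these interactions the splits were repeated after the mean of each construct over its DMSO and R libraries was taken out of each gene, a test added after the first splits were seen.

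Between WT and EV cells the response to R differed for 3 genes, and 4 of 21 splits of the samples gave as many (highest other 83), so chance was not excluded. With the construct means taken out 1 split, the real one, did (highest other 1). The 3 genes were VPS8 (0.94), BCAR1 (-1.12) and 1 that has a clone name only (1.49). The log2 fold changes in EV and WT cells were -0.10 and 0.84 for VPS8 and -0.64 and -1.76 for BCAR1.

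Between C145S and EV cells it differed for 572 genes, and 3 of 21 splits gave as many. The highest other split, with 5518 genes, exchanges all DMSO libraries of the 2 constructs and so holds the difference between constructs. With the construct means taken out 3 of 21 splits still gave as many (highest other 3630), so chance was not excluded, and counts several times the real one point to a structure of the samples. The named genes with a higher value in C145S cells were MED13L (1.64), SPPL3 (1.97), KIF21A (1.56), PEX14 (1.97), RNVU1-27 (5.07), LIN52 (1.59), STX18 (1.84), DIAPH3 (1.03), SYTL2 (1.58), RAB40C (0.92), ZFAND3 (1.64), ZBTB16 (1.04) and PLPP1 (1.299). They also included CREB3L2 (0.83), TTK (0.61), YAP1 (0.80), SOX9 (0.73), EGFR (0.68), ARHGAP35 (1.82), ZSWIM6 (0.69), SMG6 (1.54), NACC2 (0.80), E2F3 (1.45) and ZNRF3 (1.18). Those with a lower value were EID3 (-1.05), SFT2D3 (-0.77) and CHMP4BP1 (-1.49). After median-ratio scaling the calls of TTK (adjusted p = 0.0836) and RNVU1-27 (0.0954) were lost. Genes that the authors picked for a figure on these samples included MED13L, ARHGAP35, ZSWIM6, SMG6, NACC2, E2F3 and ZNRF3. KIF21A, EID3, SFT2D3 and CHMP4BP1 were chosen by their p in this interaction, and most of the others by their change with R in EV cells. The same EV libraries enter this difference, so the sign of those genes was partly set by the choice.

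Between C145S and WT cells it differed for 573 genes, and of 21 splits 1, the real one, gave as many (highest other 222; 2 with the construct means taken out, where again 1 split gave as many). This is the smallest share that 21 splits can give, so it argues against chance without excluding it. With each library left out in turn the count ran from 325 to 1253. Genes with a higher value in C145S cells were RASSF3 (2.08), BCAR1 (1.87), CUL3 (1.84), PEX14 (1.58), SPPL3 (1.78), LIN52 (1.435), STX18 (1.998), SYTL2 (1.04), RAB40C (1.90), ZFAND3 (1.55), ZBTB16 (0.88), PLPP1 (1.39) and CREB3L2 (1.05). They also included YAP1 (0.85), EGFR (0.55), ARHGAP35 (1.63), MED13L (1.48), SMG6 (1.28), NACC2 (0.70), SRSF4 (0.95), ZC3H3 (0.82), E2F3 (1.24) and ZNRF3 (1.11). Those with a lower value were GZMM (-1.72), SFT2D3 (-1.24), EID3 (-1.24) and PAWR (-0.79). Genes that the authors picked for a figure on these samples included ARHGAP35, MED13L, SMG6, NACC2, SRSF4, ZC3H3, E2F3 and ZNRF3. RASSF3, BCAR1, CUL3, GZMM, SFT2D3 and EID3 were chosen by their p in this interaction. PEX14, SPPL3 and RAB40C were among those chosen by their change with R in WT cells. The same libraries enter this difference, so the sign of those genes was partly set by the choice.

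With R in EV cells, 562 genes were lower and 81 higher by at least 2-fold. Unequal shares of 5.8S rRNA and TPM scaling may account for part of the number but not for all of it: after median-ratio scaling 250 were lower and 119 higher, so that 67.8% of such calls (65.5% to 70.6% with each of the 6 libraries left out) were still lower, and calls of any size with quantile normalization were 1651 higher and 1999 lower. Without the 3 libraries over 25% in 5.8S rRNA, 523 were lower and 96 higher. A response that needs the cysteine of NONO that C145S removes may account for part of it: over those 562 genes the change in C145S minus that in WT cells had a median of 0.53 after median-ratio scaling, 501 were above 0, and the medians were -1.03 in WT and -0.48 in C145S cells. Why these genes still fell in C145S cells stays open, and the transcript levels do not separate the expressed NONO from any of the cell's own.

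Genes of at least 200 kb were lower with R than with S in EV cells, by 0.39 (log2 -0.39) relative to genes under 50 kb after median-ratio scaling. Without scaling the difference was -0.39 as well. A factor per library moves long and short genes nearly alike, so this test cannot decide on TPM scaling and no conclusion is drawn from it. The difference was -0.38 among genes of at least 10 TPM, against the pseudocount as the cause, and at its nearest to 0 was -0.35 in a tertile of exonic length, against RNA quality acting on transcript length. A response that needs that cysteine is a candidate explanation: the R libraries of EV and WT lay 0.27 lower (log2 -0.27) than those of C145S cells, with an exact permutation p of 0.0119, the smallest that 84 splits can give. The DMSO libraries lay at 0.12, 0.10 and 0.10 in EV, WT and C145S cells, which argues against a difference present without a compound, but the S libraries gave the same p with the other sign (0.06), so that cysteine and another difference in how the 3 kinds of cells respond cannot be told apart. EV and WT cells differed between R and S by -0.42 (exact permutation p = 0.00216) and C145S cells by -0.09 (p = 0.1, the smallest that 20 splits can give).

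In DMSO, 7243 of 7303 genes called between C145S and EV cells were lower. With rRNA genes removed the median of all genes was -0.29, which argues against the rRNA share as the whole cause. A single library and the scaling may account for part of it: without C145S DMSO replicate 1, at 34.2% of TPM in 5.8S rRNA, 2721 of 2780 calls were lower, and with all libraries 983 were higher and 1772 lower after median-ratio scaling (916 and 1085 with quantile normalization; 8 and 31 when only the groups compared were fitted). So the near-total direction depended on scaling and the number on the libraries fitted, and expression of the C145S protein stays among the open explanations and was not tested apart from the libraries. Between C145S and WT cells in DMSO, 1 split set C145S DMSO replicates 1 and 3 and WT DMSO replicate 2 against the rest. It called 6588 genes against the real 3, and 2 of 10 splits called at least 3. The log2 median ratios to the mean profile were -0.464, -0.111 and -0.223 in these libraries, and 0.035 to 0.178 in the rest. That split thus follows the shift that median-ratio scaling removes, and it was not repeated after scaling.

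The 3 against 3 comparisons have 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many genes in each of those named next. For R against DMSO the real count and the highest other were 5576 and 1 in EV, 3677 and 0 in WT, and 766 and 193 in C145S cells. For S against DMSO they were 279 and 1, 214 and 1, and 338 and 1. For R against S they were 4074 and 1, 2323 and 1, and 205 and 0, and in DMSO they were 73 and 1 for WT against EV and 7303 and 6 for C145S against EV.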

How the results depend on the processing

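Removal of rRNA genes, median-ratio scaling and leaving out the 3 libraries over 25% in 5.8S rRNA were chosen after seeing the data. Of 6032 values of named genes under other settings, 5551 kept their side of the threshold, 395 lost it, 84 gained it and 2 reversed. A value that changed sign without passing in either fit was counted among the 5551. Any other change of sign was counted as reversed, whether or not the new value passed. The 377 values with a minimum fold have the estimates of the main fit. The values below are counts of called genes where no other quantity is named, and where the construction of a setting (fewer genes or fewer libraries tested, or a fold threshold) does not give the cause, the cause was not tested. Depth is unknown, so its limits were not examined.

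With quantile normalization the counts for R against DMSO were 3650 in EV and 2740 in C145S cells, and for S against DMSO 1143, 1067 and 1531 in EV, WT and C145S cells. For R against S they were 1992 in EV and 1170 in C145S cells, in DMSO 38 for WT against EV, 2001 for C145S against EV and 6 for C145S against WT, and for the interactions 105 for WT minus EV and 335 for C145S minus EV. In C145S against EV cells the log2 fold changes of MED13L and SPPL3 changed sign there, to 0.0919 and 0.0491. These small values do not show a change in the other direction. The cause was not tested.

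Without the filter the interactions gave 12 (WT minus EV) and 364 (C145S minus EV). With a pseudocount of 0.1 WT against EV gave 21 and the WT minus EV interaction 6. With a replicate block WT against EV gave 40 and the C145S minus EV interaction 366, and the replicate block changed no other count by over 1.5 times. The pairing check found no comparison in which all 3 same-numbered correlations were over 0.1 (range -0.16 to 0.10). Low correlations over all genes cannot show whether same-numbered samples were handled together, so this stays open.

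With only the libraries of the groups compared, R against DMSO gave 38 in C145S, S against DMSO 81 in WT and 81 in C145S, R against S 2632 in EV and 34 in C145S, WT against EV 6 and C145S against EV 39. The interactions gave 58 (C145S minus EV), 156 (C145S minus WT) and 0 (WT minus EV, limma; 707 at an unadjusted p under 0.05).

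With a log2 fold change of at least 1, R against DMSO gave 643, 609 and 123 in EV, WT and C145S cells, S against DMSO 90, 64 and 96, and R against S 492, 471 and 35. WT against EV gave 23 and C145S against EV 194, and the interactions C145S minus EV 158 and C145S minus WT 228. In the authors' deposited table it left 289 genes with sgSFPQ, 2 with sgPSPC, 522 with sgNONO, 1493 with sgSFPQ and sgNONO, and 723 with sgPSPC and sgNONO. At an authors' adjusted p under 0.01 sgSFPQ gave 1501 and sgPSPC 125.

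With rRNA genes removed, R against DMSO gave 7164 in WT and 2840 in C145S cells, S against DMSO 1161, 1402 and 1236, R against S 3904 in WT and 1468 in C145S, WT against EV 123 and C145S against WT 1720. The interactions gave 114 (WT minus EV) and 1853 (C145S minus WT). After median-ratio scaling R against DMSO gave 2975 in C145S, S against DMSO 1064, 1138 and 1574, R against S 2606 in EV and 1199 in C145S, WT against EV 42, C145S against EV 2755 and C145S against WT 8. The interactions gave 127 (WT minus EV) and 1058 (C145S minus WT). Without the 3 libraries over 25%, R against DMSO gave 1522 in C145S, S against DMSO 432 in EV and 331 in WT, R against S 401 in C145S, WT against EV 22, C145S against EV 3488, and the interactions 7 (WT minus EV) and 155 (C145S minus EV).

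Lists called with an estimated correlation were 0, 0 and 0 for R against DMSO in EV, WT and C145S, 2, 4 and 5 for S against DMSO, and 0, 0 and 1 for R against S. They were 1, 1 and 0 for WT against EV, C145S against EV and C145S against WT, and 0 in each interaction. With fry they were 12, 9 and 9 for R against DMSO in EV, WT and C145S, and 4, 5 and 8 for S against DMSO. They were 11, 3 and 1 for R against S, 1, 22 and 0 for the constructs in DMSO, and 0 in each interaction. With median-ratio scaling camera called 13 for R against S in EV, 13 in C145S, and 3 in the C145S minus EV interaction.

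The odds ratio of the overlap with sgNONO, lower, lost its call with the fold threshold (1.21), with R against S (1.10) and with median-ratio scaling (1.13). That with sgPSPC and sgNONO, higher, lost it with these settings (1.40, 1.70 and 1.07), and, lower, with R against S (1.11). That with sgPSPC, lower, had no call in the main setting (0.85) and was called in the other direction with R against S (1.47, Fisher's exact adjusted p = 0.00208). The cause was not tested.

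Leaving out each library in turn gave, as lowest and highest counts, 3625 and 6757 for R against DMSO in EV, 2411 and 4354 in WT, and 426 and 1185 in C145S cells. For S against DMSO these were 173 and 211 in EV, 136 and 210 in WT, and 199 and 745 in C145S, and for R against S 2200 and 5927, 1517 and 2039, and 79 and 194. In DMSO they were 17 and 211 for WT against EV, 2780 and 8993 for C145S against EV, and 2 and 168 for C145S against WT. For the interactions they were 0 and 3 (WT minus EV; limma, with 1290 at an unadjusted p under 0.05 where the count was 0, without WT DMSO replicate 1), 195 and 3551 (C145S minus EV), and 325 and 1253 (C145S minus WT).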

Other observations

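Some genes fell with R in all 3 constructs. MAD1L1, of the spindle checkpoint, fell, with log2 fold changes of -1.89 in EV, -2.02 in WT and -1.75 in C145S cells, and KCNJ3, a potassium channel subunit, with -1.33, -1.29 and -0.96. ZNRF3, a ubiquitin ligase that dampens Wnt signalling, had values of -1.18, -1.10 and 0.00 (adjusted p = 0.99 in C145S cells). The zinc finger gene ZC3H3 fell, with -1.87, -2.05 and -1.23. All 4 are genes the authors picked for a figure on these samples.

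MT1G rose with R in WT (0.61, adjusted p = 0.0261) and C145S cells (0.80, adjusted p = 0.0173) and did not pass in EV cells (0.31, adjusted p = 0.211; 0.00438 after median-ratio scaling). In the authors' deposited knockout table, genes of at least 200 kb differed from genes under 50 kb by -0.21 (median log2) with sgSFPQ, -0.33 with sgSFPQ and sgNONO, -0.00 with sgNONO alone, -0.04 with sgPSPC, and -0.04 with sgPSPC and sgNONO. The rank correlation of length with log2 fold change across genes ordered the comparisons differently: -0.326 with sgSFPQ, -0.339 with sgPSPC, 0.0645 with sgNONO, -0.0304 with sgSFPQ and sgNONO, and -0.0345 with sgPSPC and sgNONO. These values were examined after the data were seen and carry no test.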
